A study of Homo sapiens with 4 samples.

How the data were processed

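Muscle proteins at presentation and in remission were measured on 4 protein arrays with 2 colours, 2 arrays for each of 2 sample pairs, with swapped dyes. The labels do not say how the arrays were made, scanned or normalized, and these steps are not given in the sources used here. The deposited values are log2 ratios of the 2 dyes, 1 per spot and array. The file does not name the scale: it was taken from the values, because 2 to the power of a value is a ratio in steps of 0.001 for all 768 spots of every array (within 0.01 of a step), which held for at most 27 spots for a natural log and 17 for log10. The dyes of each extract come from the labels, which write the order Cy5 over Cy3 for all 4 arrays, in the descriptions and in 1 title. They do not say outright that the deposited ratio was divided in that order, and this was assumed. The median ratio is 1 on both arrays of pair 2, so that these are centred as deposited, whereas the arrays of pair 1 are not. No signal intensity or background was used here, so dim and saturated spots could not be set apart and no intensity-dependent normalization was made. All 4 columns of values were used.

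Duplicate spots were recognised from the correlation of neighbouring rows and averaged to 384 positions, named by their 2 spots. Each array was centred on the median of its positions, the ratios of arrays with remission in Cy5 were turned, the 2 arrays of a pair were averaged and the mean of the 2 pairs was taken. A position was counted as changed when this mean was at least 1.5-fold from the array median and all 4 arrays had the same sign. The planned test was limma 3.58.1 (R 4.3.3; lmFit and eBayes) of the 2 pair means against 0 with Benjamini-Hochberg adjustment at 0.05. Apart from a shift of the whole array, same-orientation arrays of the pairs differed by less than the noise between duplicate spots. The pairs were therefore counted as 1 sample, and the fit is reported only as planned. The pair number ties the swapped arrays of one pair, as the labels give it, so the averaged ratio is paired by construction. Correlations are across positions, which are not independent replicates, and carry no p-value. Other values were computed with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures with matplotlib 3.10.9.

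The fit and the 1.5-fold limit were tested on simulated data of 384 positions on 4 arrays with independent noise. Of these positions, 100 were changed 1.5-fold, 100 were changed 2-fold and 184 were unchanged. The simulated values were already turned and averaged over duplicates, so those steps and the centring were not tested. limma called 100% of the 1.5-fold, 100% of the 2-fold and 2.17% of the unchanged positions. The 1.5-fold limit kept 47% of those changed by exactly that fold, 100% of those changed 2-fold and 0% of the unchanged. No spread between pairs beyond this noise was simulated, and the noise had the same SD at every position. The real same-orientation arrays also shared deviations between duplicate spots. The simulated shares of changed and unchanged positions called therefore do not carry over to the real calls.

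Positions named in the text were chosen by a rule set before the data were examined: where positions carry no protein name, at most 2 with the highest and 2 with the lowest mean ratio among those with one sign on all 4 arrays. For the same reason the 18 protein lists planned for signalling, metabolism, muscle structure and markers of other cells were not analysed here. Alternatives covered the centring, the scale of the arrays, quantile normalization, the fold limit, duplicate spots taken singly, the variance model, the replicate unit, the direction of the ratio, and leaving out each pair and each array. Added after seeing the data were centring by grid block, averaging of same-orientation arrays, the pair as a fixed block and ratios taken as stored the same way round.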

Results

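Protein levels in human muscle were compared between presentation and remission of atypical diabetes on 2-colour protein arrays, in which extracts of both states are labelled with different dyes and bound to the same slide. The labels give 2 sample pairs, called P1 and P2 there and pair 1 and pair 2 here, and 4 arrays. Each pair was measured on 1 array with presentation in Cy5 and remission in Cy3 and on 1 array with the dyes swapped. Each array carried 768 spots in 16 grid blocks of 8 rows and 6 columns, with no missing value. Spots in rows a and b, c and d, e and f, or g and h of a block had like ratios, with Pearson correlations from 0.89 to 0.92 over 384 pairs of spots, whereas other neighbours correlated at 0.06 to 0.22. The 384 pairs of spots were therefore taken as duplicates of 384 array positions and averaged. The protein that each position captures was not analysed here, so the results below are given by position in the grid. The precision is limited by the number of arrays.

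Whether the dye swap turned the ratios was examined first. Across the 384 positions, the deposited log2 ratios of the swapped arrays went in opposite directions, with a Pearson correlation of -0.84 in pair 1 and -0.83 in pair 2. Opposite ratios are what Cy5 over Cy3 gives on swapped arrays when the dye effect is small against the difference between extracts. The descriptions order the dyes as Cy5 over Cy3, and on this basis the direction presentation over remission used below is likely. The title of the swapped array of pair 1 also writes Cy5 over Cy3, as post over pre. The labels do not say outright that the deposited values follow this order, so every direction and size below depends on that reading. Ratios divided as presentation over remission on all 4 arrays, against the order the labels write, would also be opposite on swapped arrays if the dye effect were the larger part. The half-difference of swapped arrays, which is the presentation over remission ratio by the labels, had an SD across positions of 0.23 in pair 1 and 0.21 in pair 2 on the log2 scale. The half-sum, which is the dye effect by the labels, had an SD of 0.072 and 0.069.

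**Figure D1:**
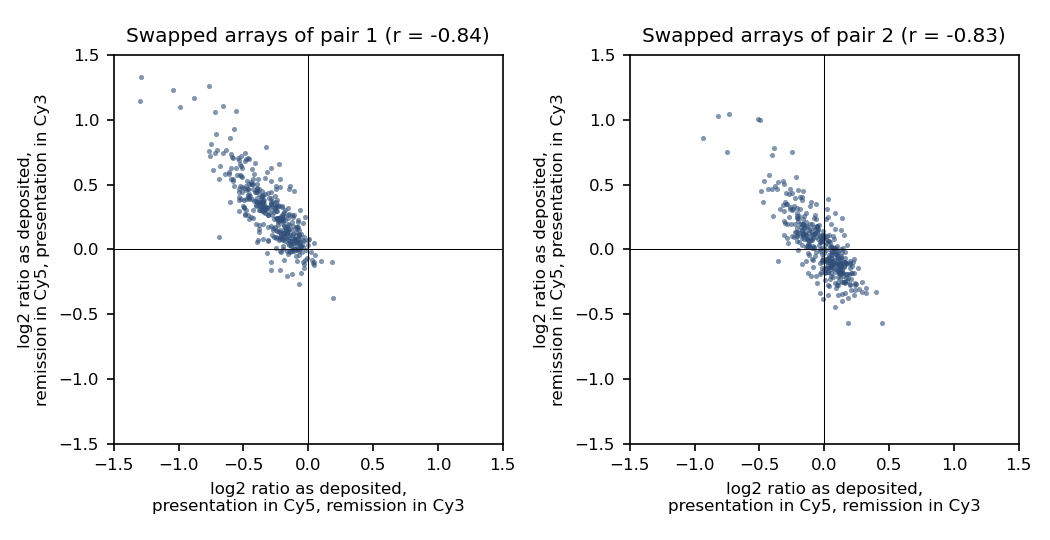
Deposited log2 ratios at 384 positions (points, each the mean of 2 duplicate spots) on the array with presentation in Cy5 (x axis) and on the array with remission in Cy5 (y axis), for pair 1 and pair 2. The ratios of swapped arrays run in opposite directions (r = -0.84 and -0.83), and the points of pair 1 are shifted from 0 on both axes.

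The pairs were then compared as replicates. Arrays of the same orientation from the 2 pairs were nearly alike: the Pearson correlation across positions was 0.98 for presentation in Cy5 and 0.98 for remission in Cy5. Apart from a shift of the whole array, the difference between these arrays had an SD across positions of 0.046 and 0.052, below the 0.061 and 0.082 that the spread between duplicate spots would give for independent spots. After a straight line was fitted between them, the remaining differences correlated between duplicate spots at 0.014 and 0.11. The deviation of the upper from the lower duplicate spot was also shared: it correlated at 0.56 and 0.72 between same-orientation arrays of the 2 pairs, but at 0.007 to 0.11 between arrays of opposite orientation. In 10000 random re-pairings of positions the highest correlation between same-orientation arrays was 0.20. Apart from the shift, arrays of one orientation thus differed by less than the noise between spots, and the 2 pairs were counted as 1 sample. Counted in this way, there is no biological replicate, and the difference between presentation and remission is described by its size. Whether the 2 pairs of the labels are truly 1 sample cannot be settled from these values. The calls of the planned fit are given only at the end.

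**Figure D2:**
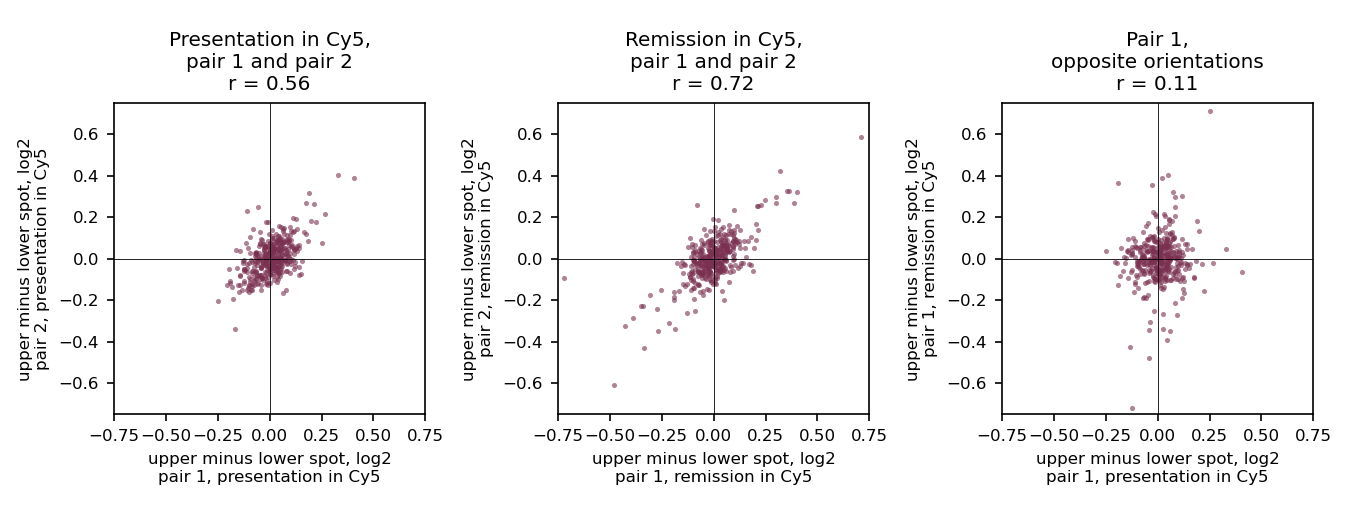
Upper minus lower duplicate spot (log2) at 384 positions (points). Deviations correlate between pair 1 and pair 2 on arrays with presentation in Cy5 (left, r = 0.56) and with remission in Cy5 (middle, r = 0.72), and hardly between the swapped arrays of pair 1 (right, r = 0.11).

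The pairs differed in the level of whole arrays. In pair 2 the median ratio of the spots was 1 on both arrays. In pair 1 it was 0.837 with presentation in Cy5 and 1.20 with remission in Cy5, so that by the labels the median spot of pair 1 was dimmer at presentation in both orientations. Each array was centred on its median for the comparisons that follow, and a difference is therefore relative to the median position.

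Relative to that median, 8 of the 384 positions differed at least 1.5-fold between presentation and remission with the same direction on all 4 arrays. All 8 were lower at presentation by the labels' direction, and none was higher. Both duplicate spots passed the same limit at 8 of these 8 positions. The lowest mean log2 ratio was at B3c1/B3d1, with -0.99 ± 0.11 (SD over 4 arrays), a 1.99-fold difference, followed by A3g4/A3h4 with -0.93 ± 0.083, a 1.91-fold difference. The highest was at D3g1/D3h1, with 0.52 ± 0.097, a 1.44-fold difference, followed by D4g4/D4h4 with 0.38 ± 0.046, a 1.3-fold difference. These SDs are technical, since the 4 arrays count as 1 sample. They also leave out the spread between duplicate spots, whose means at D4g4/D4h4 were 0.47 and 0.29. If the deposited ratios were presentation over remission on every array, none of the 384 positions would pass the limit, and the mean log2 ratio would be 0.059 at B3c1/B3d1, -0.061 at A3g4/A3h4, -0.081 at D3g1/D3h1 and 0.036 at D4g4/D4h4.

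By the labels' order, smaller differences were spread over most positions. The mean log2 ratio over the 384 positions had an SD of 0.21, with 5% of positions below -0.41 and 5% above 0.25, and the distribution had its longer tail on the lower side (skewness -1.08). The ratio had the same sign on all 4 arrays at 306 positions, 149 higher and 157 lower at presentation, where independent signs on the 2 orientations, with the pairs as repeat readings, would give 192. The technical standard error of a position's mean was 0.032, a single value pooled over the duplicate spots of all 384 positions and used for each of them. The mean was more than 2 of these errors from the array median at 305 positions, 150 higher and 155 lower. Each array was centred on its median, so near-equal numbers of higher and lower positions are largely set by the centring. If the ratios were presentation over remission on every array, the SD would be 0.069, with 5% of positions below -0.11 and 5% above 0.11 and a skewness of 0.28. The same sign on all 4 arrays would then be seen at 40 positions. With the technical error of that reading, 0.034, 92 positions would lie more than 2 errors from the median, 39 higher and 53 lower. These counts describe the repeatability of the spots and not the spread between biological samples.

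**Figure D3:**
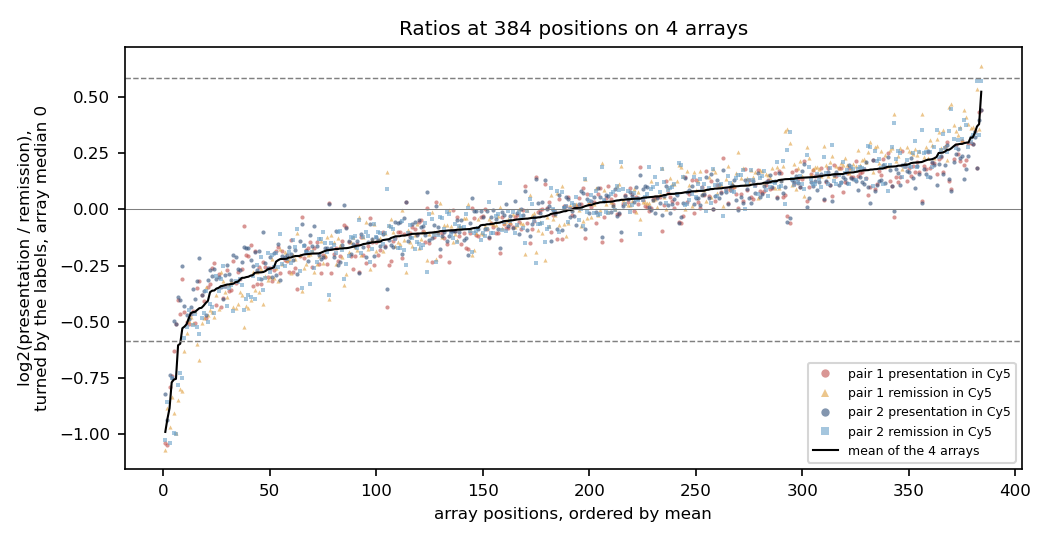
Log2 ratio of presentation over remission, turned by the labels and with each array's median at 0, at 384 positions ordered by their mean (black line). Points are the 4 arrays, and dashed lines mark 1.5-fold. The mean runs from -0.99 to 0.52, and the 8 positions past a dashed line on the mean are all at the lower end.

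Within pair 1, the mean of the swapped arrays was past 1.5-fold, with the same sign in both orientations, at 8 positions, and within pair 2 at 6 positions, all of them lower at presentation. Each orientation was past 1.5-fold by itself at 5 positions of pair 1 and 4 of pair 2. One array of pair 1 alone gave 5 positions with presentation in Cy5, all lower, and 13 with remission in Cy5, of which 12 were lower and 1, D3g1/D3h1 with a log2 ratio of 0.64, was higher. In pair 2 the single arrays gave 4 and 9, all lower. The 6 positions of pair 2 were among the 8 of pair 1, as arrays that differ, once centred, by less than the noise between spots would give. The mean log2 ratios of the pairs correlated at 0.99. Without centring, 37 positions of pair 1 and 7 of pair 2 passed, again all lower at presentation. Over both pairs the count without centring was 15, with 0 higher.

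The fit planned before the data were examined, limma on the mean ratios of the 2 pairs, treated the pairs as independent samples. It called 343 of the 384 positions, 171 higher and 172 lower, at a Benjamini-Hochberg adjusted p under 0.05, and 344 at an unadjusted p under 0.05. Apart from a shift of whole arrays, same-orientation arrays of the pairs differed by less than the noise between spots. With the pairs counted as 1 sample, these calls measure the repeatability of the readings. Their near-even split into higher and lower is largely set by the centring. The count was 55 without centring, 1 higher and 54 lower, and 7 without limma's shared variance model, 5 higher and 2 lower. With same-orientation arrays averaged first, as repeat readings, the 2 orientations gave 150 calls, 63 higher and 87 lower, which still measure technical spread alone. A sign-flip test of 2 pairs cannot give a two-sided exact p below 0.5.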

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

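The 8 positions past 1.5-fold became 15 without centring, 23 at 1.3-fold (2 higher, 21 lower), 0 at 2-fold, 16 of 768 with each spot on its own, and 0 with ratios taken as stored the same way round; scaling to one median absolute deviation, quantile normalization and block centring gave 8, 6 and 7, of which 8, 6 and 7 were among the main 8. Leaving out 1 pair or 1 array gave 6 to 9. Within pair 1 the count of 8 became 37 without centring, 26 at 1.3-fold, 1 at 2-fold, and from 5 (without remission in Cy5) to 13 (without presentation in Cy5; 1 higher) when 1 array was left out; within pair 2 the count of 6 became 22 at 1.3-fold and 0 at 2-fold. limma's 343 calls became 55 without centring, 7 without the variance model, 646 of 768 with each spot on its own, and 150 with same-orientation arrays averaged. Fitting the 4 arrays singly gave 350 without and 353 with the pair as a fixed replicate block; a random block could not be estimated from 4 arrays. The correlation of swapped arrays became -0.80 in pair 1 and -0.78 in pair 2 without the 10 largest positions, and -0.79 in pair 2 by rank; that of the pair means became 0.98 by rank and 0.99 without the 10 largest. With the ratio turned the other way, B3c1/B3d1 was at 0.99, A3g4/A3h4 at 0.93, D3g1/D3h1 at -0.52 and D4g4/D4h4 at -0.38; stored the same way round, B3c1/B3d1 was at 0.059 and D3g1/D3h1 at -0.081. Elsewhere these 4 positions kept their direction. Without centring they were at -1.12, -1.06, 0.39 and 0.25, in the order above, and D4g4/D4h4 was at 0.30 with block centring. No value was missing, so restricting to complete positions changed nothing. Set tests of the 18 lists were not run, and limma without a pair leaves no residual degrees of freedom. Leaving out the centring changes only the level of whole arrays, where the median ratio was 0.837 and 1.20 in pair 1 and 1 in pair 2. Apart from this, the fold limits and fewer or more units, the cause of each change was not tested.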

Other observations

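All tests in this part except the removal of block, row and column means were chosen after the results they bear on were seen.

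The labels describe 2 sample pairs on 4 slides, but same-orientation arrays of the pairs share the deviations between duplicate spots, which an extract does not set. A shared gradient over the slides is argued against, since the smaller correlation was still 0.58 after the mean of each block, row pair and column was removed. Print or position effects common to all slides would appear between arrays of opposite orientation too, if all kept or all reversed their sign with the swap. The largest correlation there was 0.11. A mixture of both kinds could cancel, and effects shared only by slides of one orientation were not tested, so position effects are not excluded. Like protein changes in different extracts act on both duplicates, and by themselves would leave the deviations within the random re-pairings. The highest correlation of these, 0.20, lies below both observed ones, so such likeness alone does not account for the deviations. Different extracts on slides that share spot effects could also exceed it. The deviations therefore cannot show whether the extracts differ, and like changes stay open for the position means. That one slide of each orientation was read 2 times and deposited under both pairs may explain the shared deviations, with a smaller correlation of 0.56, but this is a hypothesis from the same data that the original scans would settle.

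The swapped arrays of a pair have opposite ratios, and 2 readings of this remain. By the labels it is a difference between presentation and remission. A dye effect per position in ratios that were stored the same way round for both orientations could give the same values. The half-sum of swapped arrays, which would then be the presentation over remission ratio, correlated at 0.89 between pairs. Pairs that count as 1 sample would share this part under either reading, so the correlation decides nothing. The labels write the order Cy5 over Cy3 for all 4 arrays, which goes against the second reading if the values follow it. From the values alone the readings cannot be told apart, because the 4 arrays hold no comparison of an extract with itself.

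Ratios were wider on arrays with remission in Cy5, with an SD over spots of 0.27 in pair 1 and 0.25 in pair 2, than on those with presentation in Cy5, with 0.21 and 0.19. The noise between duplicate spots was wider there too, with an SD of 0.083 and 0.080 against 0.059 and 0.062. Of the 8 positions past 1.5-fold, 7 were farther from the array median with remission in Cy5 in both pairs, as were 204 of all 384 positions. At C2c1/C2d1, chosen after its values were seen, the turned log2 ratio was -0.51 with presentation in Cy5 and -0.99 with remission in Cy5 in pair 1, and -0.51 and -1.0 in pair 2.

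By the labels' order, the mean ratio differed between the 16 grid blocks of 24 positions each, from -0.18 in block C2 to 0.090 in block D4 (F = 3.67, permutation p = 1e-05 over 100000 permutations of positions, the smallest they can give). With ratios stored the same way round, the lowest block was B4 at -0.077 and the highest B1 at 0.050 (F = 10.8, permutation p = 1e-05, again the smallest 100000 permutations can give), with C2 at 0.033 and D4 at -0.0091, so the order of the blocks depends on the reading. Positions are not biological replicates, and centring each block on its own median left 7 of the 8 positions past 1.5-fold by the labels' order.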
